A study of Pseudomonas aeruginosa with 6 samples.

How the data were processed

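RNA sequencing counts of 6 libraries were analysed, 3 of untreated and 3 of methylrhodomelol-treated *P. aeruginosa* ATCC 27853. Groups and replicate numbers came from the sample titles. The labels name DMSO for the untreated cultures alone. Libraries were made with a directional kit (NEBNext Ultra II) from total RNA, per the labels' protocols. Trimmomatic, HISAT2, SAMtools and DESeq2 were used, per the submitters' processing notes, which give no versions; the read counter, its strand setting, the genome build and the annotation are not given in the sources used here. Reads of near-identical gene copies or of overlapping genes could therefore have been split in a way that is not known, and genes that share a product name are told apart by their identifiers.

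The authors deposited a table of raw counts per gene and library, with no normalization, and a table of their own comparison. In that table the signal columns hold group means of size-factor normalized counts, per the file headers. The log2 columns hold the fold change of treated against untreated and its standard error, the p-value columns the Wald p and its adjusted value, and the score column the Wald statistic, all per the file headers and made by the authors. Rerunning DESeq2 on the deposited counts gave log2 fold changes within 3.3e-05 of theirs. An adjusted p was given as missing for 34 genes and left so. The table of comparisons also held 80 blank lines, which were left out. All 6 count columns matched a sample title or description.

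Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of 4970 genes, 4704 passed edgeR's default filter by expression (minimum count 10, minimum total count 15). Libraries were scaled by TMM, a quasi-likelihood model with group as the only term was fitted, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) given with an edgeR log2 fold change is the size of that change divided by the square root of the test's F statistic. It was derived from the test and is not a separate measure of precision. Log2 CPM used a prior count of 2. Totals per library ranged from 3355473 to 8273195 counts, so that low genes in treated replicate 3 rest on the fewest reads. No row was named as an rRNA or tRNA gene. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 86.8, so each was counted as 1 sample.

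The test was tried on simulated counts for 4704 genes with the means, depths and spread of these libraries, with 50 genes changed at each size. edgeR called 16% of genes changed 2-fold, 90% of those changed 4-fold and 94% of those changed 8-fold, and 10 of 4504 unchanged genes. DESeq2 called 32%, 96% and 100%, and 21 unchanged genes. For changes of 2-, 4-, 8- and 16-fold, edgeR called 8, 45, 47 and 50 genes and DESeq2 16, 48, 50 and 50. Unchanged genes thus made up a share of the calls above 0.05 with both tools, and a larger share with DESeq2. With the spread of the untreated libraries alone, edgeR called 40% and DESeq2 50% of genes changed 2-fold. With flagellar genes lowered 2-fold in simulated counts, camera, camera with an estimated correlation and fry each found that list and called 0 others of 31. Each gene was simulated independently of the others, whereas the real flagellar genes had an estimated correlation of 0.254. The simulation therefore does not show how often these tests call or miss lists whose genes vary together. It also held no library that departs over many genes at once, as treated replicate 1 did. Its shares of single genes called may therefore not hold for the real libraries. There, an aldehyde dehydrogenase (PGD117602617) with an 8.39-fold fitted change had an edgeR adjusted p of 0.052.

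Before the data were examined, 34 gene lists were fixed: pyoverdine; pyochelin; haem and other iron; quorum sensing; quorum-controlled exoproducts; phenazines; types II, III and VI secretion; flagella; chemotaxis; type IV pili; efflux; oxidative stress; electrophile and quinone detoxification; SOS response; pyocins; protein folding; AlgU and alginate; lipid A modification; exopolysaccharides; NADH dehydrogenases and terminal oxidases; ATP synthase; denitrification; citrate cycle; ribosomal proteins; fatty acid synthesis; aromatic catabolism; branched-chain amino acid and acyclic terpene catabolism; sulfate starvation; zinc and copper; phosphate starvation; cell wall and division; stationary phase. The deposited table gives product names, and none of its identifiers was in the reference table of names. The lists held 1218 symbols. Genes were matched to them by product name, which gave 645 genes in 650 list memberships, 212 by a symbol inside the product name and 438 through 311 product names mapped by hand; where several genes share a product name, several were matched to 1 symbol. That mapping was written after the deposited comparison had been seen and before any list was tested. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. fry asks whether a list's genes move one way on balance and does not compare them with other genes.

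Genes were named by a rule fixed in advance. It takes the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 20 CPM in the higher group, a name and groups that do not overlap; the 4 members of each tested list with the smallest adjusted p; and 9 regulators and controls, of which 6 (rhlR, exsA, algU, rpoS, recA, ampC) were matched and the others are not analysed here. An informative product name stood in for a symbol. Since 2 genes passed edgeR, the first part was also applied to the authors' table, which was decided after its values had been seen. Genes named for values in 1 library were likewise chosen after their values were seen.

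The alternatives were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 3 libraries, the 10 most abundant genes left out, the replicate number as a block, and each library left out in turn. edgeR's earlier moderation, lists matched by symbol alone, DESeq2 without each library, and the estimated correlation without each library and with the block were added after seeing the data. Figures were drawn with matplotlib.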

Results

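RNA was sequenced from *Pseudomonas aeruginosa* ATCC 27853, a wild-type reference strain used in antibiotic susceptibility testing. Cultures were started from pre-cultures of about 18 h and grown at 37 °C to mid-log phase in Vogel-Bonner minimal medium, in which citrate is the carbon source. The treated cultures received 75 µM methylrhodomelol, a brominated phenol made by red algae, and the untreated cultures received 0.1% DMSO. Whether the treated cultures also held DMSO is not stated in the labels. By the labels, an effect of methylrhodomelol and one of a difference in DMSO therefore cannot be told apart. Each group held 3 libraries, and reads were reported as counts for 4970 genes. The untreated libraries held 8015929, 8273195 and 5413085 counts and the treated libraries 6069197, 4999098 and 3355473, for replicates 1 to 3 of each group. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

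The comparison asked how the transcriptome of treated bacteria differed from that of untreated bacteria at 1 time point. A quinoprotein ethanol dehydrogenase (PGD117602621), which oxidises alcohols in the periplasm, rose 10.8-fold, from 6.64 ± 2.60 to 72.2 ± 21.0 counts per 1000000 counts of the scaled library (CPM; mean ± SD, n = 3). The cobalamin-independent methionine synthase (PGD117602740), annotated as 5-methyltetrahydropteroyltriglutamate--homocysteine methyltransferase, was 28.6-fold lower, at 63.5 ± 39.5 CPM in treated and 1820 ± 517 CPM in untreated libraries (SD, n = 3). It makes the last step of methionine synthesis without vitamin B12. Both genes separated all 3 treated from all 3 untreated libraries, and both had the same edgeR adjusted p = 0.0324, with log2 fold changes of 3.43 ± 0.37 and -4.84 ± 0.50 (SE). The lowest count of the dehydrogenase in any library was 24 and that of the methionine synthase 129.

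These were the 2 genes of 4704 tested that passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 1 higher and 1 lower, and both changed at least 2-fold. At an unadjusted p under 0.05 there were 444 genes, 295 higher and 149 lower, and 8 genes had an adjusted p under 0.1. Treated and untreated libraries did not overlap for 623 genes, or 13.2% of those tested, against 10% by chance; 340 of these were higher and 283 lower in treated libraries. The test called 463 genes when treated replicate 1 was left out, 231 higher and 232 lower, and both genes were among them. It called 0 genes without untreated replicate 1, 2 or 3, with 488, 273 and 320 genes at an unadjusted p under 0.05, and DESeq2 then called 116, 51 and 65. Without treated replicate 2 it called 1 gene and without treated replicate 3 it called 3.

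DESeq2's Wald test on the same counts called 93 genes, and all 93 were the calls of the authors' deposited table: 65 higher, 28 lower and 88 changed at least 2-fold. Of these genes, 89 had groups that did not overlap, all 93 had an unadjusted p under 0.05 in edgeR, and 82 were among the 463 genes called by edgeR without treated replicate 1. With 1 library left out, DESeq2 called between 46 genes, without treated replicate 3, and 829 genes, without treated replicate 1. It called 51 genes without untreated replicate 2. Apart from the ethanol dehydrogenase and the methionine synthase, these genes missed the threshold in edgeR, whose adjusted p is given beside those named.

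Among the genes that the rule named as higher in the authors' deposited table, the 3 largest log2 fold changes were those of the ethanol dehydrogenase at 3.42, an aldehyde dehydrogenase (PGD117602617) at 3.06 and the cytochrome c-550 PedF at 3.00, an electron carrier of periplasmic alcohol oxidation. The aldehyde dehydrogenase measured 3.92, 7.12 and 5.82 CPM in untreated and 67.0, 48.0 and 26.3 CPM in treated libraries, and PedF 2.33, 3.81 and 2.63 CPM against 31.2, 25.0 and 14.2 CPM; both had an edgeR adjusted p of 0.052. In all 3 genes treated replicate 1 held the highest value. Acetyl-coenzyme A synthetase, which activates acetate, had a log2 fold change of 2.53 and an alcohol dehydrogenase 2.13 in the authors' deposited table, with edgeR adjusted p of 0.112 and 0.163. Acetyl-CoA synthetase stood at 58.5, 121 and 83.7 CPM in untreated and 285, 745 and 509 CPM in treated libraries. A biotin carboxylase subunit annotated to acetyl-CoA carboxylase (PGD117608556; 2.77) and a lactonizing lipase (2.52), a secreted triacylglycerol hydrolase, were also higher in the authors' deposited table, with edgeR adjusted p of 0.169 and 0.163. The biotin carboxylase subunit measured 249 CPM in treated replicate 1 and 1793 and 1230 CPM in treated replicates 2 and 3, against 133 to 185 CPM in untreated libraries.

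Terminal oxidases of the respiratory chain had opposite directions in the authors' deposited table. Subunits I and II of the cytochrome bd-type ubiquinol oxidase, a quinol oxidase that bypasses the cytochrome c branch, had log2 fold changes of -1.80 and -1.75 in the authors' deposited table, with an edgeR adjusted p of 0.052 for each. Subunit I measured 1611, 1440 and 1338 CPM in untreated and 347, 520 and 409 CPM in treated libraries. Cytochrome c oxidase subunit I, of the branch that takes electrons from cytochrome c, was higher by 2.73 in the authors' deposited table and subunit 3 by 1.76, with edgeR adjusted p of 0.196 and 0.266. In treated replicate 1 these subunits stood at 7.58 and 7.27 CPM, near the untreated maxima of 5.84 and 6.12 CPM, and in treated replicates 2 and 3 between 25.0 and 36.8 CPM. Of the 27 tested NADH dehydrogenase and terminal oxidase genes, 2 higher and 2 lower passed when adjusted over the list alone, the same numbers as in the authors' deposited table. The list as a whole did not pass camera (adjusted p = 0.962).

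Of the 27 tested sulfate starvation genes, 4 were lower in the authors' deposited table. The aliphatic sulfonate permease SsuC had a log2 fold change of -2.68, alkanesulfonate monooxygenase -2.36, taurine dioxygenase -2.32 and a molybdopterin-binding protein (PGD117598977) -2.19 in the authors' deposited table. SsuC imports sulfonates, and the monooxygenase and the dioxygenase release sulfite from sulfonates. Their edgeR adjusted p were 0.163, 0.229, 0.163 and 0.142. SsuC measured 383, 281 and 403 CPM in untreated libraries, 108 CPM in treated replicate 1 and 34.2 and 24.2 CPM in treated replicates 2 and 3. Of the 27 tested members of the sulfate starvation list, 17 had a fitted value below 0; 8 had treated libraries all below the untreated ones and 1 all above. None passed edgeR over all genes tested, 11 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 4. Without treated replicate 1, edgeR called 10 lower and 1 higher. Adjusted over the list alone, 4 were lower and 1 higher. Camera with its preset correlation placed the list lower (adjusted p = 4.39e-05; adjusted p = 0.905 with an estimated correlation), with a median log2 fold change of -0.31. The list median relative to the untreated mean was 0.04 in treated replicate 1, and -1.17 and -1.14 in treated replicates 2 and 3.

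Further genes lower in the authors' deposited table were the pseudopaline transporter CntI (-2.94), which takes part in zinc acquisition, an ABC transporter permease (PGD117601790; -2.50), an ABC transporter ATP-binding protein (PGD117601788; -2.39), an MFS transporter (PGD117608644; -2.03) and a PepSY domain protein (-1.78). CntI measured 119, 213 and 65.7 CPM in untreated and 7.88, 40.2 and 4.33 CPM in treated libraries. The remaining genes named by the rule as higher in the authors' deposited table were 4-hydroxyphenylpyruvate dioxygenase (2.44), homogentisate 1,2-dioxygenase (2.30), the multidrug resistance operon repressor (2.27) and a TetR family regulator (2.63). Their edgeR adjusted p were 0.147, 0.163, 0.112 and 0.186, and those of the 5 lower genes in this paragraph, in the order given, 0.299, 0.114, 0.243, 0.144 and 0.141.

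**Figure D1:**
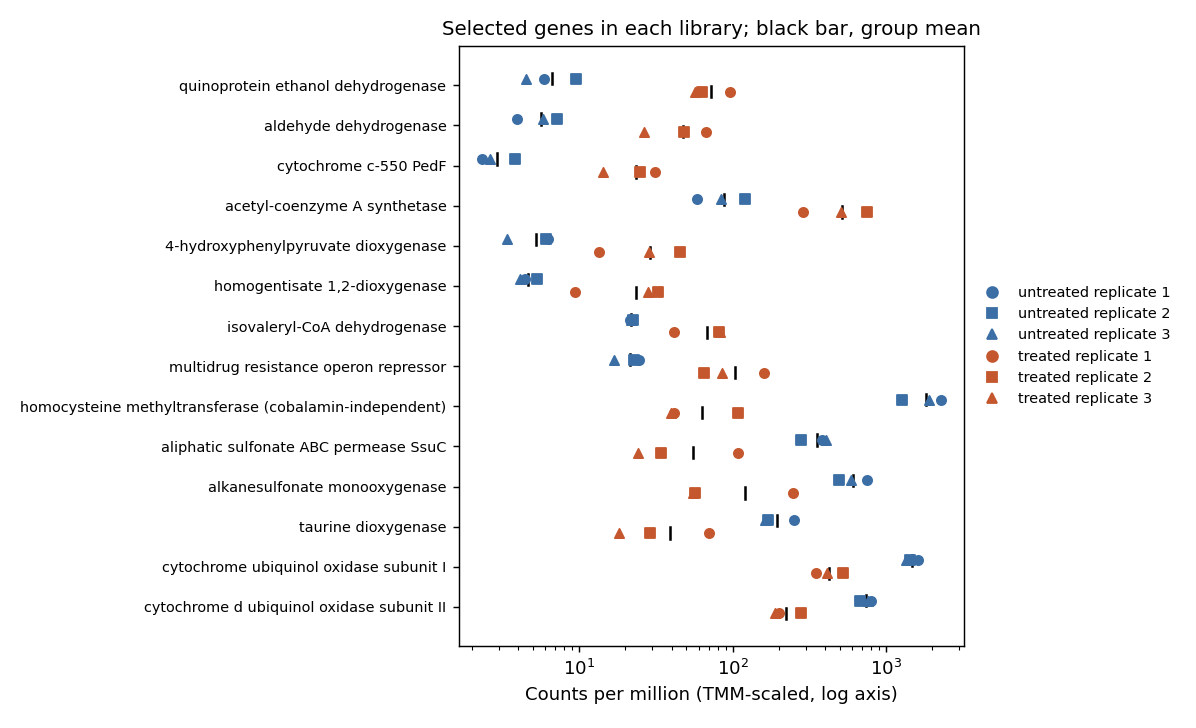
CPM (TMM-scaled, log axis) of 14 genes in each of the 3 untreated and 3 treated libraries; symbols are libraries and black bars are group means. The ethanol dehydrogenase lay between 57.0 and 96.0 CPM in treated libraries and at 9.53 CPM or less in untreated ones, and the homocysteine methyltransferase at 109 CPM or less in treated libraries and at 1266 CPM or more in untreated ones.

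Libraries did not group fully by treatment. The first principal component of log2 CPM held 48.5% of the variance and placed treated replicates 2 and 3 at 30.03 and 33.7, treated replicate 1 at -19.6 and the untreated libraries at -11.1, -15.0 and -18.1. Treated replicate 1 had a mean correlation of 0.960 with the untreated libraries and 0.930 with the other treated libraries, which correlated with each other at 0.982. These correlations run across genes, which are not independent replicates. The ethanol dehydrogenase (96.0 CPM) and the methionine synthase (41.4 CPM) of treated replicate 1 lay with the treated group. The 10 most abundant genes took 8.73% of counts in treated replicate 1, 12.1% in treated replicate 2, 15.4% in treated replicate 3 and between 9.33% and 10.8% in untreated libraries. In treated replicate 3, 1 of these genes, the RNA polymerase subunit beta', alone took 4.65%.

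**Figure D2:**
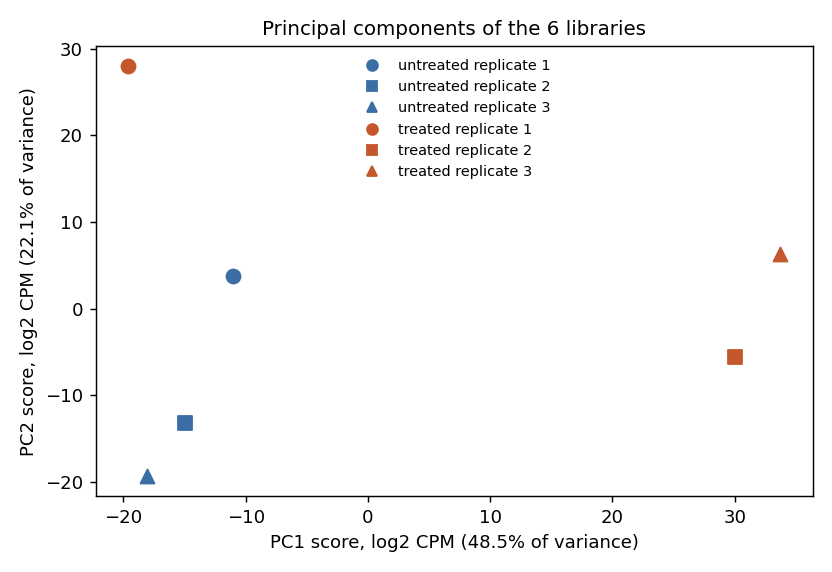
Scores of the 6 libraries on the first (48.5% of variance) and the second (22.1%) principal component of log2 CPM; each symbol is 1 library. Treated replicate 1 lies at -19.6 on the first component, beyond the lowest untreated score of -18.1, and treated replicates 2 and 3 lie at 30.03 and 33.7.

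The list symbols were fixed before the data were examined. Of 650 list memberships, 438 were mapped by hand after the deposited comparison had been seen. Among 621 tested genes matched to the lists, edgeR called 0 over all genes tested. Of them 59 had an unadjusted p under 0.05, 32 higher and 27 lower. Limma-voom called 0, DESeq2 called 20, and edgeR called 72 without treated replicate 1, among them 11 of sulfate starvation, 7 of the citrate cycle, 7 of ribosomal proteins, 6 each of fatty acid synthesis, aromatic compound catabolism and the cell wall, and 5 of the branched-chain list. Camera with its preset correlation of 0.01 placed 3 of 31 lists past the threshold, and none of the 3 held with an estimated correlation or with fry. Leaving out treated replicate 1 gave 7 lists, and 0 lists passed with an estimated correlation whichever library was left out.

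Genes of branched-chain amino acid and acyclic terpene catabolism were placed higher as a list by camera with its preset correlation (adjusted p = 2.56e-07, and adjusted p = 0.508 with an estimated correlation). All 12 members were mapped by hand from product names, after the deposited comparison had been seen. Of 12 tested members, 11 had a fitted value above 0, 5 had treated libraries all above untreated ones, and 5 were higher when adjusted over the list alone. None passed edgeR over all genes tested, 7 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 4. Camera kept this call without each library in turn, with adjusted p between 1.92e-08 and 3.43e-05. Isovaleryl-CoA dehydrogenase (PGD117602557) measured 21.4, 22.5 and 21.6 CPM in untreated and 41.4, 81.2 and 83.0 CPM in treated libraries, a log2 fold change of 1.65 ± 0.30 (edgeR SE; adjusted p = 0.141). The beta subunit of methylcrotonyl-CoA carboxylase (PGD117602559) stood at 1.09 ± 0.22 and a gene annotated as gamma-carboxygeranoyl-CoA hydratase (PGD117602561) at 0.94 ± 0.22 (SE). Their edgeR adjusted p were 0.163 and 0.196. Whether this hydratase acts in terpene breakdown, as its name says, was not examined. The list median was 0.80, and relative to the untreated mean it was 0.54, 0.94 and 0.79 in treated replicates 1 to 3.

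Flagellar genes were placed lower as a list by camera with its preset correlation (adjusted p = 0.00805, and adjusted p = 0.905 with an estimated correlation). At that preset, 9 of 10 splits of the libraries gave 3 or more lists, the real split included. Of 39 tested members, 32 had a fitted value below 0, 5 had treated libraries all below and 1 all above untreated ones, and none passed when adjusted over the list alone; 1 had an unadjusted p under 0.05 and DESeq2 called 0. The list median relative to the untreated mean was -0.003 in treated replicate 1, -0.31 and -0.30 in treated replicates 2 and 3, and -0.21 in untreated replicate 1. The median of the fitted values was -0.26, with the basal body protein FliE at -0.98 ± 0.38 and the motor proteins MotB at -0.50 ± 0.22 and MotA at -0.41 ± 0.20 (SE). The call was lost without untreated replicate 2 (adjusted p = 0.29) and without treated replicate 2 (adjusted p = 0.0694). For chemotaxis genes, 13 tested, the camera adjusted p was 0.825, and CheA stood at -0.31 ± 0.23 (SE). Type IV pilus genes, 13 tested, had a median of 0.12 and a mean of 0.01 while camera's direction was down (adjusted p = 0.962), and up with upper-quartile scaling. The pilus protein FimU stood at -0.47 ± 0.25 (SE).

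Breakdown of aromatic compounds, 25 genes tested, had 15 fitted values above 0 and did not pass camera (adjusted p = 0.333); 2 members were higher and 1 lower when adjusted over the list alone. The higher members were 4-hydroxyphenylpyruvate dioxygenase (2.45 ± 0.47) and homogentisate 1,2-dioxygenase (2.32 ± 0.46), consecutive enzymes of tyrosine breakdown, and the lower one the reductase subunit of 4-hydroxyphenylacetate 3-monooxygenase (-1.13 ± 0.28, SE). Homogentisate dioxygenase measured 4.13 to 5.34 CPM in untreated libraries, 9.39 CPM in treated replicate 1 and 32.6 and 27.9 CPM in treated replicates 2 and 3. Citrate cycle and glyoxylate shunt genes, 28 tested, gave a camera adjusted p of 0.962 with the direction up. Without treated replicate 1 the direction was down (adjusted p = 0.341) and edgeR called 6 lower and 1 higher. One malate:quinone oxidoreductase (PGD117598955) stood at -1.03 ± 0.31 and another (PGD117606807) at 0.69 ± 0.22 (SE), each with groups that did not overlap. The 9 ATP synthase genes had a median of 0.21 and a mean of 0.16 while camera's direction was down (adjusted p = 0.962); relative to the untreated mean the list median was 1.05 in treated replicate 1 and -0.77 and -0.41 in treated replicates 2 and 3. Without treated replicate 1, camera placed ATP synthase genes lower (adjusted p = 0.00452; adjusted p = 0.886 with an estimated correlation) and edgeR called 1 of the 9 members. Denitrification and anaerobic growth genes, 25 tested, gave an adjusted p of 0.775, with the accessory protein NosL at -1.75 ± 0.45 (SE) and at most 6.12 CPM. Fatty acid synthesis genes, 26 tested, had a median of -0.06 and a mean of 0.06 (camera direction down, adjusted p = 0.775), and the median was above 0 with upper-quartile scaling or library totals alone.

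Efflux genes, 22 tested, went both ways and gave a camera adjusted p of 0.962; 2 were higher when adjusted over the list alone. These were the multidrug resistance operon repressor (2.28 ± 0.37), the name of the MexAB-OprM pump's regulator, and a MexA family periplasmic adaptor (1.23 ± 0.27, SE), with edgeR adjusted p of 0.112 and 0.169. The adaptor measured 379, 403 and 370 CPM in untreated and 1250, 730 and 719 CPM in treated libraries. The permease MexW stood at -0.57 ± 0.18 and the exporter NorM at -1.19 ± 0.40 (SE). The list median of 0.01 was below 0 with RLE scaling. Electrophile and quinone detoxification genes had 15 of 18 fitted values above 0 (median 0.33; camera adjusted p = 0.0976, and adjusted p = 0.905 with an estimated correlation). Camera placed them higher with the filter of 10 CPM (adjusted p = 0.0421) and without treated replicate 1 (adjusted p = 0.022, and adjusted p = 0.703 with an estimated correlation), where edgeR called 3 higher. A glutathione-independent formaldehyde dehydrogenase measured 6.73 to 7.51 CPM in untreated and 12.1, 18.0 and 18.3 CPM in treated libraries and was the 1 member higher when adjusted over the list alone. Oxidative stress defence, 31 genes tested, gave an adjusted p of 0.648, with glutathione peroxidase at 0.48 ± 0.22 (SE). SOS response and DNA repair, 20 tested, gave 0.248, with RecX at -0.60 ± 0.27, and the recombinase RecA, the inducer of the response, stood at -0.07 ± 0.20 (SE; above 0 with upper-quartile scaling). Pyocin genes, 4 tested, gave 0.248, and protein folding and proteolysis, 28 tested, 0.404. Without untreated replicate 2, camera placed protein folding and proteolysis past the threshold (adjusted p = 0.0309; adjusted p = 0.992 with an estimated correlation). The chaperone GroES measured 20260 CPM in treated replicate 3, 4069 CPM in treated replicate 1 and between 665 and 1940 CPM in the other libraries.

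Zinc and copper genes, 21 tested, had 14 fitted values below 0 and a camera adjusted p of 0.0976. With the replicate number as a block, camera called them lower (adjusted p = 7.12e-05, and adjusted p = 0.987 with an estimated correlation). Camera placed them lower without treated replicate 2 (adjusted p = 3.54e-05; adjusted p = 0.591 with an estimated correlation) and without treated replicate 3 (adjusted p = 0.0323; adjusted p = 0.991 with an estimated correlation). CntI had a log2 fold change of -2.91 ± 0.81, GTP cyclohydrolase FolE2 of -2.93 ± 1.17 and a copper chaperone (PGD117601009) of 1.08 ± 0.36 (SE). FolE2 measured 36.1, 143 and 17.1 CPM in untreated and 2.42, 22.4 and 0.619 CPM in treated libraries. Iron-related groups did not pass, as far as genes were matched: 5 for 30 pyoverdine symbols and 17 for 50 haem and other iron symbols. The 5 pyoverdine genes gave a camera adjusted p of 0.558 and the 15 tested haem and other iron genes 0.648. The pyoverdine synthetase PvdL was the most abundant gene by CPM summed over all libraries. It stood at -0.14 ± 0.39, and a bacterioferritin (PGD117607372) at 1.54 ± 0.59 (SE). Phosphate starvation genes, 17 tested, gave 0.331, and 1 was higher when adjusted over the list alone. That gene, a glycerol-3-phosphate transporter ATP-binding protein named UgpC, measured 160, 288 and 265 CPM in untreated and 861, 763 and 746 CPM in treated libraries (1.73 ± 0.27, SE; edgeR adjusted p = 0.101).

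The virulence and quorum sensing genes that could be matched and tested did not pass as lists or singly. None had an unadjusted p under 0.05 in edgeR or a call by limma-voom or DESeq2. Without treated replicate 1 edgeR called 4 type VI secretion genes. Matching was partial: 6 genes for 20 quorum sensing symbols, 12 for 27 exoproduct symbols, 17 for 42 type III and 33 for 69 type VI secretion symbols. The regulators lasR and pqsR were not matched, so the unmatched genes remain unexamined. Camera adjusted p were 0.962 for 5 quorum sensing genes, 0.678 for 11 quorum-controlled exoproducts, 0.648 for 17 type III secretion genes, and 0.962 for 33 type VI and 9 type II secretion genes. The regulator RhlR stood at -0.03 ± 0.35 (SE; above 0 with upper-quartile scaling), the elastase at -0.28 ± 0.36, the chitinase at -0.62 ± 0.27 and the type III secretion activator ExsA at -0.12 ± 0.39 (SE). With upper-quartile scaling the medians of the quorum sensing, exoproduct and chemotaxis lists were above 0 and otherwise below 0, except that library totals alone also put the exoproduct and chemotaxis medians above 0. Type II secretion had a median of 0.08 and a mean of 0.01 while camera's direction was down. Camera placed type III secretion genes lower without untreated replicate 1 (adjusted p = 2.7e-07; adjusted p = 0.824 with an estimated correlation), the library with the lowest list median, -1.60 relative to the untreated mean. A type VI secretion effector annotated to the Hcp1 family (PGD117601670), 1 of 5 Hcp genes in the list, measured 6.67 CPM in treated replicate 1, 46.4 and 36.2 CPM in treated replicates 2 and 3 and between 7.88 and 15.6 CPM in untreated libraries. Fewer than 4 members were tested for pyochelin (2), phenazines (1) and exopolysaccharides (2), which had no list test.

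Envelope and growth groups did not pass camera on the edgeR fit with all 6 libraries. Cell wall and division genes, 30 tested, gave a camera adjusted p of 0.221, and 0.00978 without treated replicate 1 (adjusted p = 0.886 with an estimated correlation), with RodA at -0.51 ± 0.30 (SE). The beta-lactamase AmpC, annotated as PDC-5, stood at 0.31 ± 0.29 and the envelope stress sigma factor AlgU, annotated as sigma-H, at 0.34 ± 0.31 (SE). AlgU and alginate genes, 15 tested, had a median and a mean of 0.04 while camera's direction was down (adjusted p = 0.962). Lipid A modification genes, 12 tested, gave 0.248, with the outer membrane protein H1 at -0.80 ± 0.32 (SE). Ribosomal protein genes had 39 of 50 fitted values below 0 and a camera adjusted p of 0.0976. Camera placed them lower with limma-voom (adjusted p = 0.0378), without treated replicate 1 (8.72e-05) and without untreated replicate 3 (0.00025). The adjusted p = 0.978 with an estimated correlation on all 6 libraries, 0.886 without treated replicate 1 and 0.944 without untreated replicate 3. Stationary phase genes, 14 tested, gave 0.648. The ribosome modulation factor measured 3555 and 3422 CPM in treated replicates 2 and 3, 291 CPM in treated replicate 1 and between 473 and 1058 CPM in untreated libraries, and the sigma factor RpoS stood at 0.47 ± 0.38 (SE).

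**Figure D3:**
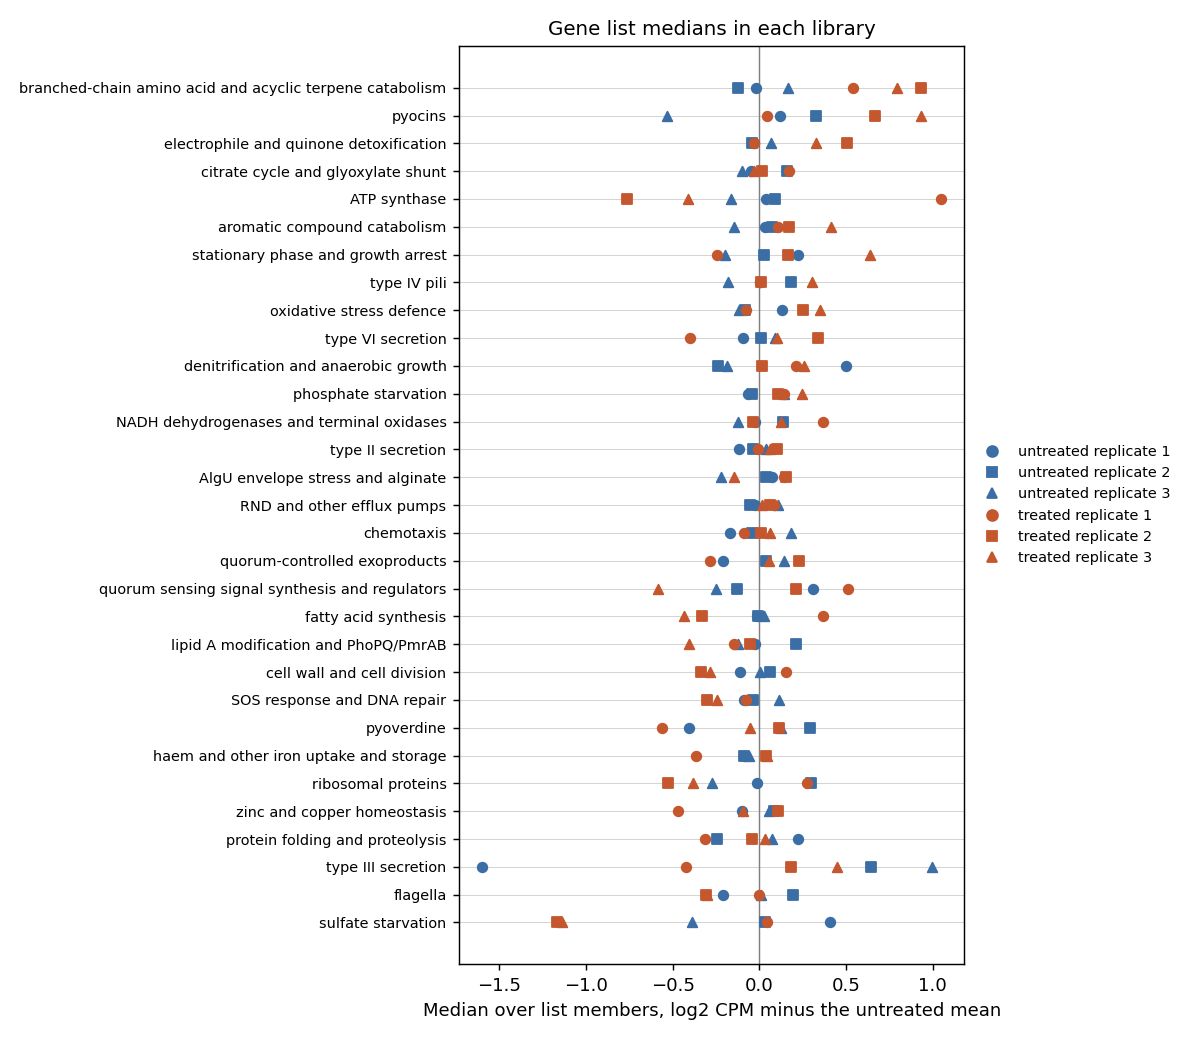
Median over the tested members of each of 31 gene lists, as log2 CPM minus the untreated mean, in each library; symbols are libraries. Treated replicates 2 and 3 lie at -1.17 and -1.14 for sulfate starvation and treated replicate 1 at 0.04, and for branched-chain amino acid and acyclic terpene catabolism the treated libraries lie at 0.54, 0.94 and 0.79.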

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

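edgeR's earlier moderation, lists matched by symbol alone, DESeq2 without each library, and the estimated correlation without each library and with the block were chosen after seeing the data. With upper-quartile factors, library totals alone, limma-voom, no filter, the filter of 10 CPM, the 10 most abundant genes left out or the earlier moderation, both genes stayed past the threshold with no others. RLE scaling called 7 genes, 4 higher and 3 lower, all 7 at least 2-fold and all 7 meeting the naming rule. DESeq2 called 93, 65 higher and 28 lower, 88 at least 2-fold, with 24 genes named by the rule. Both genes were among the calls of RLE and of DESeq2, and the cause of the differing counts was not tested.

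Leaving out 1 library gave 0 to 463 changed genes in edgeR (0 to 231 higher, 0 to 232 lower, 0 to 327 at least 2-fold, 0 to 24 named) and 3 to 7 lists. The count was 0 without untreated replicate 1, 2 or 3, where edgeR had 488, 273 and 320 genes at an unadjusted p under 0.05, 1 without treated replicate 2, 3 without treated replicate 3 and 463 without treated replicate 1. DESeq2 gave 116, 51 and 65 genes without untreated replicates 1 to 3 and 829, 77 and 46 without treated replicates 1 to 3, and 90 of the 93 were among the 829. Fewer libraries leave fewer degrees of freedom; the cause of the higher counts without treated replicate 1 was not tested.

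Of the lists, 3 passed under every scaling, with DESeq2, without a filter and with symbol matches alone, and 4 with limma-voom, ribosomal proteins added (adjusted p = 0.0378), and with the filter of 10 CPM, electrophile detoxification added (adjusted p = 0.0421). With fry 0 passed, and with an estimated correlation 0 passed, with all libraries, without each library in turn and with the replicate block. With symbol matches alone the branched-chain list had no members and zinc and copper passed (adjusted p = 0.0107). Otherwise the branched-chain and sulfate starvation lists passed camera with its preset correlation under every alternative run, and flagella failed without untreated replicate 2 and without treated replicate 2. No named gene or list that was past the threshold in either fit changed direction. The correlation of treated replicate 1 with the untreated libraries was 0.961 after DESeq2's variance-stabilising transformation.

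With the replicate number as a block, edgeR called 8 genes, 3 higher and 5 lower, all 8 at least 2-fold and 5 of them named by the rule, and 4 lists passed, zinc and copper (adjusted p = 7.12e-05; adjusted p = 0.987 with an estimated correlation) beside the 3 others. Same-numbered libraries deviated together by correlations of 0.017, 0.037 and -0.075, so the numbers were not taken as pairs, and not every library correlated best with its own number. Depth limits genes near the floor, such as PedF, whose lowest count was 14. edgeR called 16% of 2-fold changes simulated with the spread of both groups and 40% with that of the untreated libraries. In those simulations genes varied independently and no library departed as treated replicate 1 did, so these shares may not hold here.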

Other observations

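The tests of a mislabelled sample and of slower growth below were chosen after the library correlations had been seen.

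Several genes were abundant in a single library. At 10 or more times the next library and at least 100 CPM there were 6 such genes. The 50S ribosomal protein L22 measured 26170 CPM in treated replicate 2, 2.61% of that library, and at most 607 CPM elsewhere. The RNA polymerase subunit beta' took 4.65% of treated replicate 3, at 48210 CPM against 4494 CPM in the next library, and a PqiB family protein stood at 7256 CPM there against 270 CPM. In untreated replicate 2 an ABC transporter substrate-binding protein (PGD117604999) and a cell division protein (PGD117607702) stood at 9019 and 7405 CPM, against 577 and 718 CPM in the next library. A type 1 fimbrial protein measured 167 CPM in treated replicate 1 and at most 10.2 CPM elsewhere. A phosphate ABC transporter ATP-binding protein (PGD117608400) measured 628 CPM in treated replicate 1 and between 61.5 and 87.5 CPM in the other libraries.

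Type III secretion genes differed widely within the untreated group. The adenylate cyclase effector ExoY measured 200 CPM in untreated replicate 1 and 1403 and 1943 CPM in the other untreated libraries, against 228, 1045 and 1128 CPM in treated replicates 1 to 3. The list median was -1.60 in untreated replicate 1 and 0.65 and 1.00 in untreated replicates 2 and 3, relative to their mean. A DksA protein (PGD117608766) and FolE2 were both highest in untreated replicate 2 and lowest in treated replicate 3: DksA stood at 31.6, 73.6 and 7.32 CPM in untreated and 4.70, 12.8 and 0.619 CPM in treated libraries.

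Treated replicate 1 correlated more with the untreated libraries than with the other treated libraries, and edgeR called 463 genes without it. The tables argue against depth as the cause, since after every library was thinned to 3355473 counts its mean correlation was still higher with the untreated libraries by 0.0329, more than the range of 0.0108 of its 3 correlations with them. An untreated library under a wrong label stays open on a test over 200 genes. These best separated treated replicates 2 and 3 from 2 untreated libraries. The median place of treated replicate 1 between them minus that of the held-out untreated library ran from -0.104 to 0.0358 in 3 fits. That is within the range of 0.184 of the untreated places, so this test cannot decide. Of these genes, 23%, 20.5% and 18.5% in treated replicate 1 lay nearer the treated group, against 21.5%, 6% and 10% in the held-out untreated library. The methionine synthase of treated replicate 1 stood at 41.4 CPM, against 1266 to 2290 CPM in untreated libraries. The ethanol dehydrogenase of that library stood at 96.0 CPM, against 4.5 to 9.53 CPM. Both genes also passed edgeR without treated replicate 1, and for these 2 genes the values argue against a wrong label. Slower growth of the cultures of treated replicates 2 and 3 stays open too, as a hypothesis: both had lower ribosomal protein medians than the other 4 libraries, by at least 0.108 (gap -0.108, log2), which is less than the distance from -0.28 to 0.30 between untreated libraries, and edgeR gave the ribosome modulation factor a log2 fold change of 2.14 without treated replicate 1. That factor is 1 of 14 tested stationary phase genes. Their list median was 0.17 and 0.64 in treated replicates 2 and 3, against 0.22 in untreated replicate 1. Without treated replicate 1 that list did not pass camera (adjusted p = 0.0749), and edgeR called 4 members higher. A weaker response of treated replicate 1 may account for the pattern as well and was not tested, but it was not weaker in every gene. Its ethanol dehydrogenase, at 96.0 CPM, was above the 63.4 and 57.0 CPM of treated replicates 2 and 3, and its PedF, at 31.2 CPM, above 25.0 and 14.2 CPM. The biotin carboxylase subunit went the other way (249 against 1793 and 1230 CPM), as did the sulfate starvation median (0.04 against -1.17 and -1.14).

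The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 2 genes and 2 genes changed at least 2-fold, the highest other split 0 and 0, so that 1 of 10 splits reached the real count of genes and 1 of 10 that of genes changed at least 2-fold. At an unadjusted p under 0.05 the real split gave 444 genes, and the split of untreated replicate 1 with treated replicates 2 and 3 gave 931. Untreated replicates 1 and 2 with treated replicate 1 gave 636, and untreated replicates 1 and 3 with treated replicate 1 gave 567. For lists, the real split gave 3 and the highest other 10, and 9 of 10 splits gave 3 or more, the real one included. With an estimated correlation the real split and each of the others gave 0 lists.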
